A study of Mus musculus with 13 samples.

How the data were processed

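Mouse leukaemia cell lines 748T, 106A, 961C and the SCL-LMO1 line were examined by chromatin immunoprecipitation sequencing in 13 samples. Of these, 9 came with a peak list: 4 for H3K4me3, 4 for H3K27me3 and 1 for V5-tagged NP23 in 961C. The 4 input samples had no list and were not used here. Per the labels' protocols, chromatin was fixed with formaldehyde and sonicated, immunoprecipitated with antibodies to H3K4me3, H3K27me3 or V5, and sequenced with single-end reads on GAIIx or MiSeq instruments. Which instrument served which library is not given in the sources used here. Per the submitters' processing notes, CASAVA 1.9 and BWA 0.5.9-r26 were used with genome build mm9. The peak caller and its thresholds are not given in the sources used here.

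Each list deposited by the authors holds regions of 1 library, with start, end and a text field. From the values, starts count from 0 and ends are not included. The text field gives the mean and the maximum pileup height of the sample over the region, and the mean and maximum of a second track. The letter that marks the second track is not explained, and it was read as a background track from its low values alone. Over the 9 lists, 5 of 109165 rows lack the second track. Heights are whole-number maxima and show no scaling to depth, so heights were compared within a list only. The narrowest peak in any list is 80 bp and the shortest gap between peaks is 150 bp. Without read totals, the depth per library is unknown, and the number and height of the listed peaks are what limits precision.

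Samples were grouped by the labels' cell type and antibody. Lines 748T and 106A are samples 1 and 2 of the NP23 pre-T group, and every other group has 1 sample. Group differences were therefore not tested. Peaks were compared by an overlap of at least 1 bp. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Overlap of NP23 with a mark, and of lists with each other, was set against 1000 random placements of the peaks within their own chromosome, lengths kept, with the furthest peak end in any list standing in for the chromosome length. Placement was even along the chromosome and took no account of where reads can map or genes lie. NP23-bound H3K4me3 peaks were set against 1000 random sets of unbound ones drawn to the same number in each of 10 width classes, with replacement where a class held too few. The widest class has no upper limit, and every H3K4me3 peak of 10 kb or more held NP23, so matching was looser there. Where only some NP23 peaks entered, unbound meant free of those, and comparison peaks could hold other NP23 peaks. The median width of bound peaks was set against 1000 draws of as many points as there are overlapping NP23 peaks, placed on H3K4me3 peaks in proportion to width. Permutation p-values, two-sided, were taken from the ranks among the 1000 values, with a threshold of 0.05, and their smallest possible value is 0.0020. Regions over several lists were formed by merging overlapping peaks.

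Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The placement step was tested on simulated data with 1567 NP23-length peaks, of which 56.8% were planted in H3K4me3 peaks and 57.1% were recovered as overlapping, and without planted overlap 4.50% of simulated lists passed the threshold. The width-matched sets, tested on the 17696 H3K4me3 peaks with simulated labels, passed it in 4.00% of runs. The chance of a simulated label rose evenly with width rank. NP23 in the data held 23.6% of H3K4me3 peaks under 200 bp, 0.779% at 1 to 2 kb and 100% at 10 kb or more. The 4.00% therefore does not cover that setting.

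Before the data were examined, 10 widest H3K4me3 peaks of 961C with NP23 and 10 widest H3K27me3 peaks of each line were chosen for naming. Also chosen were the 10 NP23 peaks with the highest score of the authors, or the 10 widest if no score was given. The lists give no score. The 10 tallest NP23 peaks by maximum height were named instead, a choice made after the files were seen. Other regions were named after their values were seen. The lists of genes and promoters chosen before the data were examined were not used, because the gene table at hand is for assembly GRCm38.p6 and the peaks are on mm9. Regions are therefore given by coordinate, and what genes lie in them was not analysed here. Alternatives tried were coverage of at least 50% of the NP23 peak, the taller 50% of NP23 or mark peaks, circular shifts in place of free placement, autosomes alone, other or no width matching, lists reduced to equal numbers of peaks, joining of peaks within 1 kb, and leaving out each NP23 pre-T line. Added after seeing the data were limits on NP23 width (500 bp) and second-track height (1 read), classes of H3K4me3 width, and 100 width classes for matching.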

Results

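Binding of the NUP98-PHF23 fusion protein (NP23) and 2 histone marks were mapped by chromatin immunoprecipitation and sequencing in 4 mouse leukaemia cell lines. NUP98 is a nuclear pore protein and PHF23 carries a PHD finger, a protein fold that can bind histone H3 trimethylated at lysine 4. H3K4me3 is the mark of active promoters, and H3K27me3 is the repressive mark laid down by Polycomb complexes. Lines 748T and 106A were derived from NP23 pre-T LBL of different mice and formed a group of 2 samples per mark. Line 961C was derived from an NP23 acute myeloid leukaemia (AML). The SCL-LMO1 line, from a pre-T LBL driven by SCL and LMO1 on a hybrid strain background, was the control without the fusion. Each line had 1 H3K4me3 and 1 H3K27me3 peak list, and 961C had 1 NP23 list from an antibody against the V5 tag. No antibody was repeated within a line, so the p-values below describe these libraries and not a population of cultures. Coordinates are mm9.

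The H3K4me3 lists were alike in size and the H3K27me3 lists were not. H3K4me3 peaks numbered 17544 in 748T, 16324 in 106A, 17696 in 961C and 17616 in the SCL-LMO1 line, and covered 20.4 to 21.9 Mb. H3K27me3 peaks numbered 8412, 5600, 19469 and 4875 in the same order and covered 2.24, 1.54, 8.86 and 1.202 Mb. The median H3K27me3 peak was 204 to 289 bp wide, against 1013 to 1133.5 bp for H3K4me3. The 1629 NP23 peaks of 961C covered 0.808 Mb with a median width of 164 bp. The lists give heights of read pileups and no read totals, so the depth of each library is unknown. The median peak reached 10 to 12 reads in every H3K27me3 list, 13 reads in the NP23 list, 38 reads in H3K4me3 of 961C and 76 to 97 reads in H3K4me3 of the other lines.

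The series asks how the marks relate to NP23 binding. In 961C, most listed NP23 peaks overlapped H3K4me3: 1173 of 1629 (72.0%, 95% interval 69.8 to 74.2), 59.1 times the 1.22% of randomly placed peaks. H3K4me3 of 748T, 106A and the SCL-LMO1 line overlapped 23.7%, 23.9% and 23.3% of the same NP23 peaks, so the pre-T lines with and without the fusion differed by less than their counting intervals. Within 961C the share rose with the width of the NP23 peak, from 51.6% of peaks under 150 bp to 303 of 304 peaks (99.7%) of 500 bp or more. Those 304 peaks made up 18.7% of the list and 70.9% of the bases it covered. NP23 peaks under 500 bp gave 870 of the 1173 overlaps. Some of these short peaks may come from stretches that collect reads in every 961C library. The 72.0% and the 59.1 times therefore cannot be read as binding alone. Each H3K4me3 share was above all 1000 random placements (permutation p = 0.0020, the smallest that 1000 placements can give, two-sided).

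**Figure D1:**
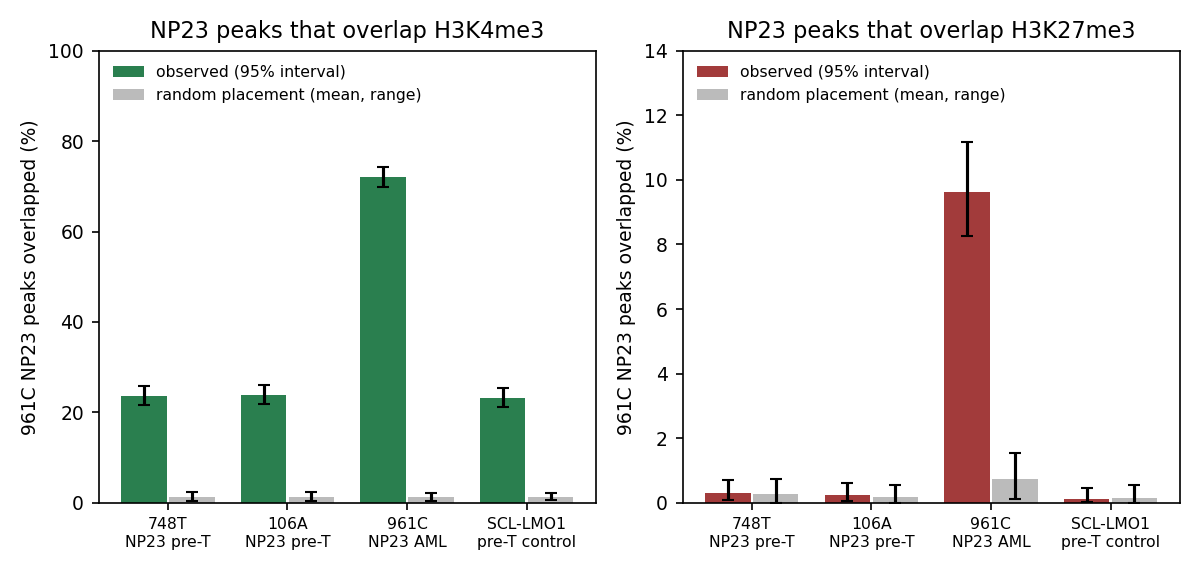
Share of the 1629 NP23 peaks of 961C that overlapped an H3K4me3 peak (left) or an H3K27me3 peak (right) of each line, in percent. Coloured bars are observed shares with exact 95% intervals, grey bars the mean of 1000 random placements with their lowest and highest value, and the y axes differ. The share was 72.0% for H3K4me3 and 9.64% for H3K27me3 in 961C itself, and H3K27me3 of the other lines lay within the range of the placements.

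NP23 occupied the broadest H3K4me3 domains of 961C and a set of very short H3K4me3 peaks, and was rare in between. All 15 H3K4me3 peaks of 10 kb or more held an NP23 peak (lower bound of the 95% interval 78.2%), as did 14 of the 15 peaks of 8 to 10 kb (93.3%) and 44 of the 168 peaks of 4 to 5 kb (26.2%). Among the 5778 peaks of 1 to 2 kb the share was 0.779% (0.569 to 1.04), and among the 3604 peaks of 0.5 to 1 kb it was 0.638%. It was again 23.6% (21.7 to 25.5) in the 1931 peaks under 200 bp. In all, 877 of 17696 H3K4me3 peaks (4.96%) held NP23.

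Because 568 of these 877 were under 500 bp, the median width of NP23-bound H3K4me3 peaks was 184 bp. It lay below the 1665.5 to 1892 bp found when the same number of points was placed at random over the H3K4me3 peaks (permutation p = 0.0020, the smallest possible with 1000 placements). The direction turned when only NP23 peaks of 500 bp or more were counted, a choice made after seeing the data: the median was then 4192.5 bp against 1615 to 2059 bp. It turned as well when only the taller 50% of mark peaks entered, with 3468 bp against 1916 to 2196 bp.

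**Figure D2:**
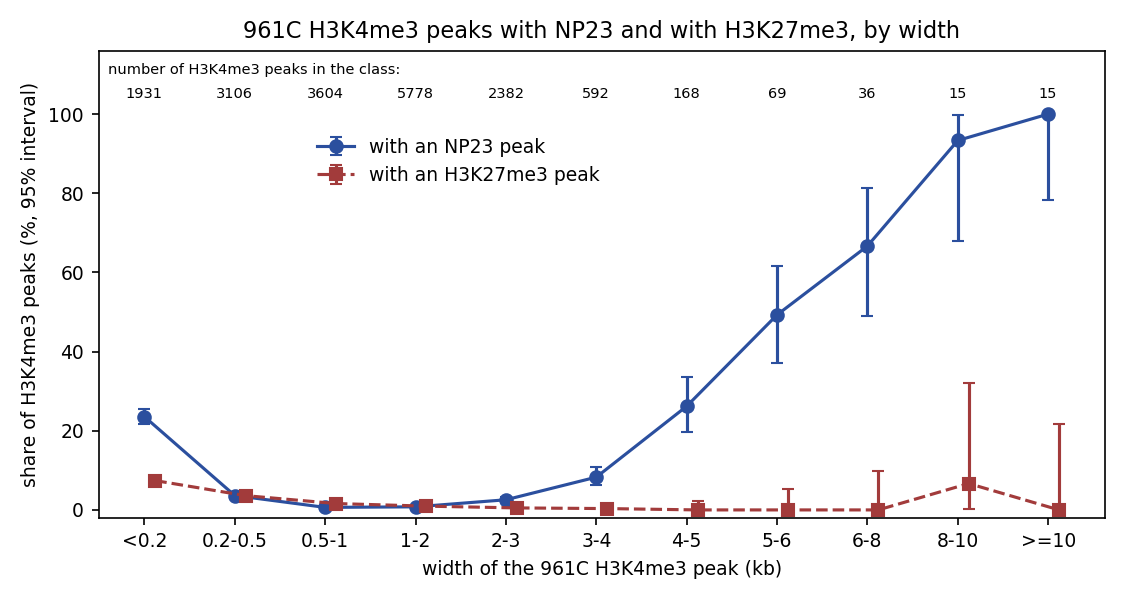
Share of 961C H3K4me3 peaks with an NP23 peak (circles) and with an H3K27me3 peak (squares) by width of the H3K4me3 peak in kb. Error bars are exact 95% intervals for counting error, and the number of H3K4me3 peaks in each class stands at the top. The NP23 share was 23.6% under 0.2 kb, under 1% from 0.5 to 2 kb, and 100% at 10 kb or more.

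The widest NP23-bound H3K4me3 peak lay on chromosome 11 from 96132114 to 96184711, 52598 bp long and 97.1% covered by 4 NP23 peaks, of which the longest was 37347 bp. The next widest, on chromosome 6 from 52156421 to 52185551 (29131 bp), was 98.2% covered by NP23. On chromosome 6 the domain was shared by the fusion lines: H3K4me3 covered 80.1% of it in 748T and 78.1% in 106A, and no H3K4me3 or H3K27me3 peak of the SCL-LMO1 line fell in it. On chromosome 11 the pre-T lines differed from 961C. H3K4me3 covered 7.42% of that domain in 748T, 2.57% in 106A and 2.09% in the SCL-LMO1 line. Over the surrounding 100 kb (96100001 to 96200000), 748T had 12 H3K27me3 peaks, 106A had 22 and the SCL-LMO1 line had 7, while 961C had 0.

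**Figure D3:**
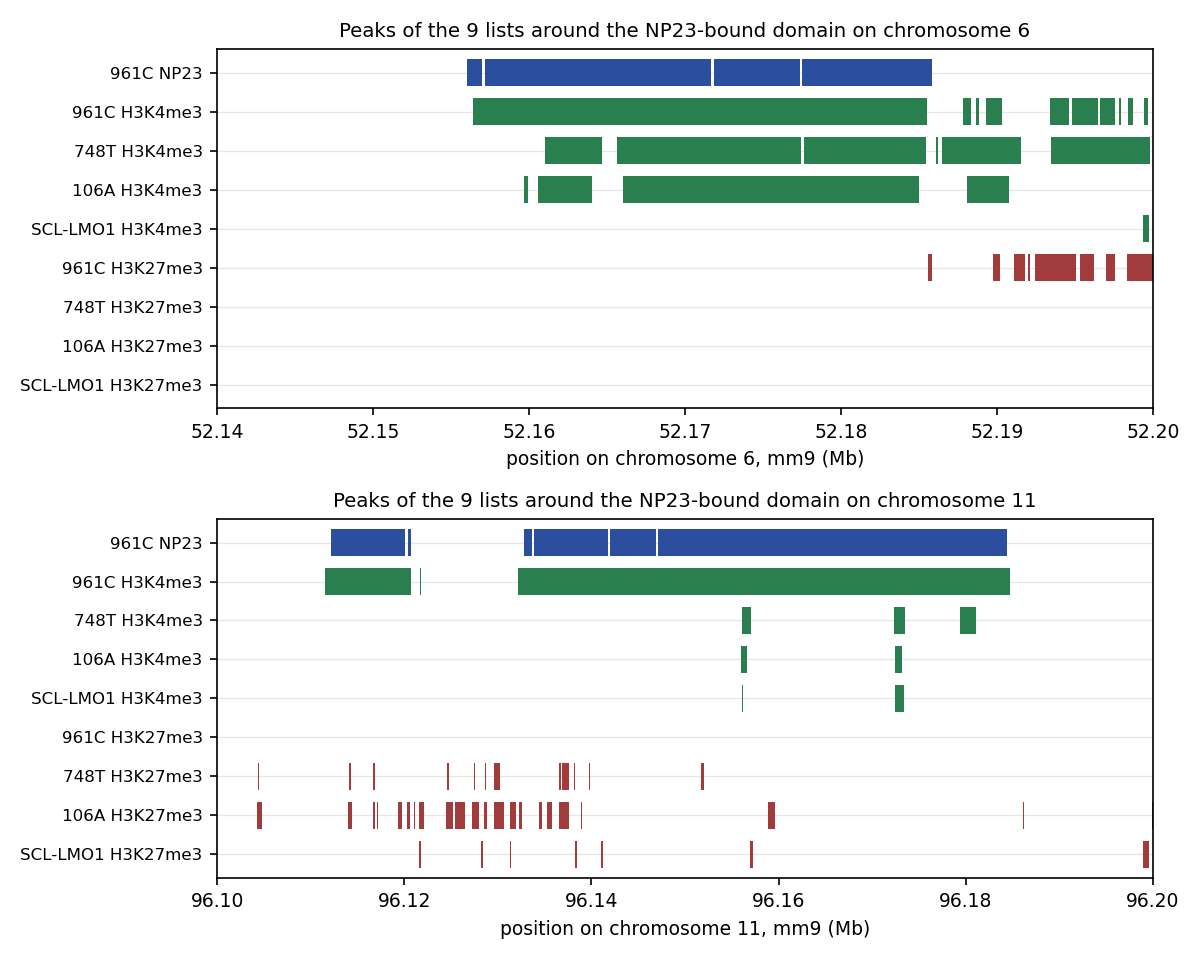
Peaks of the 9 lists around the widest NP23-bound domains, on chromosome 6 (top) and chromosome 11 (bottom), with mm9 position in Mb on the x axis and a list in each row. Blue bars are NP23 peaks, green H3K4me3 and red H3K27me3, all drawn to scale. On chromosome 6 the domain carried H3K4me3 in 961C, 748T and 106A, and on chromosome 11 the pre-T lines carried short H3K27me3 peaks (12, 22 and 7 in 748T, 106A and the SCL-LMO1 line).

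The other 8 of the 10 widest NP23-bound H3K4me3 peaks were 11769 to 16793 bp wide. They lay on chromosome 11 (starting at 22745217, 79879518, 18906962, 79332261 and 60587078), chromosome 14 (32628722 and 32971920) and chromosome 3 (58217725). NP23 covered 73.6% to 92.0% of each. In 7 of these 8 the other 3 lines had narrower H3K4me3, from 7.06% of the 961C domain in the SCL-LMO1 line on chromosome 14 at 32628722 to 46.5% in 106A on chromosome 3. The exception, chromosome 11 from 18906962 to 18920935, carried 6 NP23 peaks and no H3K4me3 peak of any other line. None of these 8 held an H3K27me3 peak in any line.

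The tallest NP23 peaks were of another kind. Of the 10 with the highest pileup, 9 were under 1 kb, 6 overlapped an H3K27me3 peak of 961C and 2 overlapped H3K4me3 of another line. The tallest, on chromosome 7 (85058548 to 85058839) and chromosome 14 (9439002 to 9439286), each reached 103 reads. Their second-track means were 8.66 and 5.60 reads, against a median of 0.134 over all NP23 peaks. The peak on chromosome 3 from 58219065 to 58225801, with a maximum of 82 reads, was the only one also among the 10 widest.

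NP23 and H3K27me3 met seldom in 961C, and mostly at short peaks. H3K27me3 overlapped 157 of 1629 NP23 peaks (9.64%, 8.25 to 11.2), above the 0.123% to 1.53% of random placements (permutation p = 0.0020). The share was 148 of 1325 (11.2%, 9.52 to 13.0) for NP23 peaks under 500 bp, with 5.21% under 150 bp and 25.2% from 150 to 200 bp, and 9 of 304 (2.96%, 1.36 to 5.55) for those of 500 bp or more, where it no longer differed from random placement (permutation p = 0.192). Of the NP23 peaks, 1031 (63.3%) met H3K4me3 alone, 142 (8.72%) both marks, 15 (0.921%) H3K27me3 alone and 441 (27.1%) neither. The class with neither had a median width of 105 bp.

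From the side of H3K4me3, of 877 NP23-bound H3K4me3 peaks, 138 (15.7%, 13.4 to 18.3) overlapped H3K27me3, against 2.22% of unbound H3K4me3 peaks of matched width (highest of 1000 sets 3.53%, permutation p = 0.0020). Of these 138, 132 were under 500 bp. In the broad class of 2 kb or more, chosen after seeing the data, 1 of 241 bound peaks (0.415%, 0.0105 to 2.29) had H3K27me3, against 0.182% of matched unbound peaks (permutation p = 0.727). With only NP23 peaks of 500 bp or more the excess remained, at 7 of 190 bound peaks (3.68%) against 0.808% of matched ones (highest set 3.16%, permutation p = 0.0020). It rests on few peaks, and the comparison peaks could hold shorter NP23 peaks. NP23 peaks of this width with both marks included chromosome 17 from 39984281 to 39985175 and chromosome 4 from 129912066 to 129912634. Their second-track means were 9.85 and 3.76 reads, against a median of 0.310 for NP23 peaks of 500 bp or more.

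At the NP23 sites of 961C, broad H3K4me3 peaks mostly met an H3K4me3 peak in the other lines and short ones mostly did not. An overlap of 1 bp counts here, and how much of the 961C peak was covered did not enter. In 748T, 106A and the SCL-LMO1 line, coverage was 7.42%, 2.57% and 2.09% of the widest domain, on chromosome 11. For the next widest, on chromosome 6, it was 80.1%, 78.1% and 0%. Of 241 NP23-bound H3K4me3 peaks of 2 kb or more, 91.7% overlapped H3K4me3 in 748T, 90.9% in 106A and 88.8% in the SCL-LMO1 line. Matched unbound peaks gave 89.7% (permutation p = 0.204), 86.6% (permutation p = 0.0120) and 87.7% (permutation p = 0.591). Width matching was loose here, since all 15 H3K4me3 peaks of 10 kb or more were bound. In this class bound peaks had a median width of 4244 bp and unbound ones, before matching, 2477 bp. A remaining difference in width may therefore enter these values. Of 568 bound peaks under 500 bp, 4 were marked in 748T, 2 in 106A and 3 in the SCL-LMO1 line, against 33.6% to 35.9% of matched unbound peaks. Over all 877 bound peaks the shares were 29.5%, 29.1% and 28.8%, below 54.0%, 51.7% and 52.9% of matched unbound peaks (permutation p = 0.0020 in each line). With NP23 peaks of 500 bp or more, also chosen after seeing the data, bound peaks stayed below matched ones: 81.6% against 88.7% in 748T (permutation p = 0.0020), 80.5% against 85.8% in 106A (permutation p = 0.0300) and 78.9% against 86.9% in the SCL-LMO1 line (permutation p = 0.00599). No difference between the fusion lines and the control line was tested, since each has 1 library per mark.

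H3K27me3 of the other lines was nearly absent from these sites. It overlapped 4 of 877 NP23-bound H3K4me3 peaks in 748T (0.456%), 2 in 106A (0.228%) and 1 in the SCL-LMO1 line (0.114%), within the matched sets (permutation p = 0.915, 0.707 and 1). Of the 6 NP23 peaks that met H3K27me3 in another line, 4 lay on chromosome 11 between 96112201 and 96184458, in the region described above. The remaining 2 were short, on chromosome 14 (9439002 to 9439286) and chromosome 6 (124722849 to 124722978).

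The 3 pre-T lines shared most of their H3K4me3, with or without the fusion. Of 106A peaks, 83.0% (82.4 to 83.6) overlapped 748T and 83.3% (82.7 to 83.8) overlapped the SCL-LMO1 control, and 81.1% of 748T peaks overlapped the SCL-LMO1 line. Base-pair Jaccard indices of these pairs were 65.7%, 64.6% and 66.1%. The myeloid line 961C stood further away: 70.4% of 748T, 72.6% of 106A and 66.5% of SCL-LMO1 peaks overlapped it, with Jaccard indices of 52.1% to 53.9%. The H3K4me3 peaks of 961C were also lower, with a median of 38 reads against 76 to 97. Since depth is unknown, cell type and library cannot be told apart here. By Jaccard index 106A was nearer to 748T than to the control (65.7% against 64.6%), and 748T was nearer to the control than to 106A (66.1% against 65.7%).

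**Figure D4:**
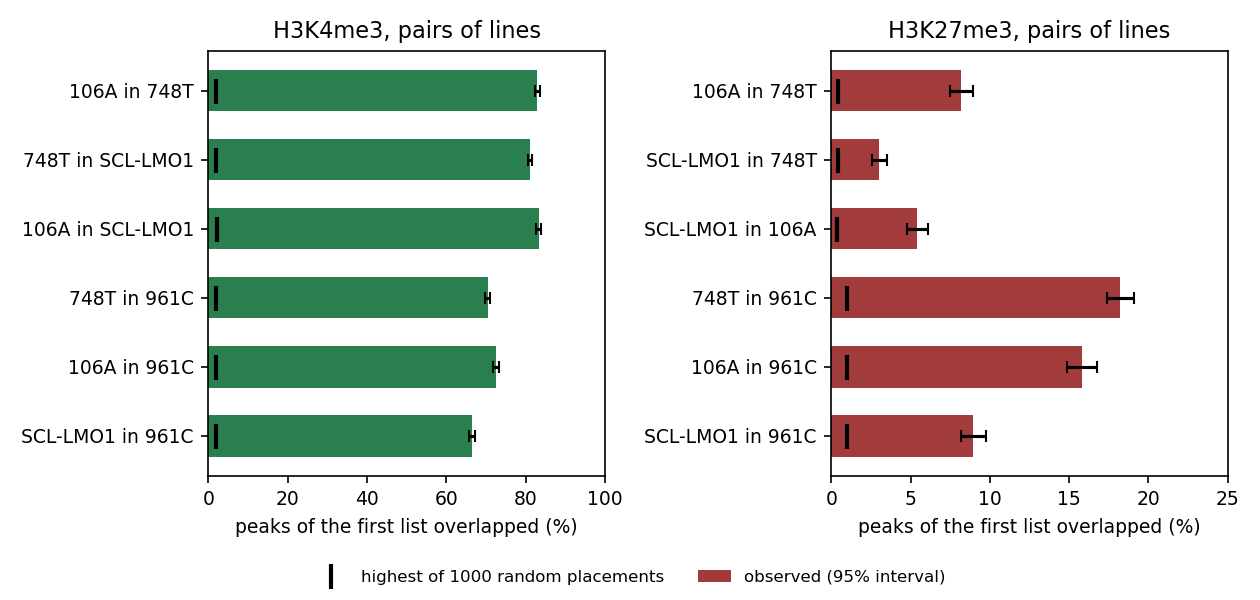
Share of peaks of the first line that overlapped a peak of the second, in percent, for H3K4me3 (left) and H3K27me3 (right), with exact 95% intervals for counting error. The list with fewer peaks is named first, black ticks mark the highest of 1000 random placements, and the x axes differ. H3K4me3 shares ran from 66.5% to 83.3% and H3K27me3 shares from 3.02% to 18.2%.

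Merged over the 4 lines, H3K4me3 formed 25059 regions, of which 9463 (37.8%) were present in all 4. The number present in the 3 NP23 lines and missing in the SCL-LMO1 line was 352. The same count was 157 with 748T as the missing line, 520 with 106A and 1433 with 961C. The figure for the SCL-LMO1 line therefore lay inside the range over the NP23 lines, and in this line oncogene and mouse strain differ together. It depended on the pair of pre-T lines: requiring 748T without 106A gave 798 regions, and 106A without 748T gave 497.

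NP23 was bound in 961C at 5 of the 352 regions (1.42%, 0.463 to 3.28), which were named after their values were seen. These were chromosome 6 from 52156421 to 52185551, 51952513 to 51963659 and 51473492 to 51475515, chromosome 19 from 32828950 to 32837606, and a 212-bp region on chromosome 11 at 5907549. H3K4me3 found in 961C alone formed 4447 regions, 612 of them (13.8%, 12.8 to 14.8) with NP23. Of the 197 that were 2 kb or wider, 17 (8.63%, 5.11 to 13.5) held NP23. Regions of all 4 lines held NP23 at 2.45%, and at 4.57% where 2 kb or wider. The 612 take in most of the 568 bound H3K4me3 peaks under 500 bp. Some of those may come from stretches that collect reads in every 961C library. The widest regions of 961C alone were chromosome 11 from 18906962 to 18920935 and chromosome 5 from 143576293 to 143585469, and the latter held no NP23 peak. Of the 1433 regions of the 3 pre-T lines missing in 961C, none held NP23 (upper bound 0.257%). NP23 was mapped in 961C alone, and most of its peaks lie in H3K4me3 of 961C, which these regions lack by definition. The low count therefore follows largely from how the regions were chosen. The widest of these 1433 regions, chromosome 11 from 52086405 to 52101043, carried 4 H3K27me3 peaks in 961C, and the next 4 widest carried 1, 0, 1 and 0.

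H3K27me3 peaks were mostly private to a line. Of 106A peaks, 8.20% (7.49 to 8.95) overlapped 748T, and 5.42% and 3.02% of SCL-LMO1 peaks overlapped 106A and 748T. The longer list of 961C took in 18.2% of 748T, 15.8% of 106A and 8.94% of SCL-LMO1 peaks, and 13.5%, 9.46% and 3.96% with all lists reduced to equal numbers of peaks. Every pair was above its random placements, by 14.7 to 40.7 times. Regions found in a single line numbered 6542 in 748T, 4318 in 106A, 17170 in 961C and 4206 in the SCL-LMO1 line, of 34848 in all, and 46 were present in all 4 lines.

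The widest H3K27me3 peak of 961C, chromosome 11 from 118903000 to 118913558, was also the widest region marked in all 4 lines, with 5 peaks in 748T, 9 in 106A and 1 in the SCL-LMO1 line. The widest in 106A was chromosome 3 from 88009537 to 88015164 (5628 bp), where 961C had 6 peaks, the SCL-LMO1 line had 4 and 748T had 0. The widest in 748T, chromosome 5 from 141066427 to 141069109 (2683 bp), was private to that line. In the SCL-LMO1 line, 7 of the 10 widest peaks lay on chromosome 16 between 91054399 and 95680144, among them the widest (92363326 to 92365783).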

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

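All tests in this part were chosen after the result they bear on was seen. The second track, which enters no test above, stood out in 3 places. Its median height was 5.47 reads over the 10 tallest NP23 peaks, against 0.282 over the 10 widest. In 748T its height over H3K4me3 peaks was 1.47 times the autosomal level on chromosome 15 and 1.46 times on chromosome 14, where the other lines gave 0.990 to 1.098 and 0.922 to 0.998.

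Short NP23 peaks in short H3K4me3 peaks of 961C may come from stretches that collect reads in every library of that line. H3K27me3 met 23.2% of NP23-bound H3K4me3 peaks under 500 bp, against at most 4.93% in width-matched unbound sets. High background is a candidate explanation for a part of them: the second track exceeded 1 read at 18.0% of these bound peaks, against at most 4.58% in the matched sets, and was 0 at 51.2%, against 52.6% to 63.9%. The part is limited. With only NP23 peaks of second-track mean at most 1, H3K27me3 still met 13.95% of 767 bound H3K4me3 peaks of any width, against 2.73% of matched ones. At most 0.704% of the bound short H3K4me3 peaks were marked in any other line, below the lowest matched set (28.7%), which binding at sites private to the AML line would give as well. The excess of H3K27me3 cannot decide between such stretches and private binding, since NP23 sites that carry both marks would give it as well. NP23 peaks under 500 bp also matched their H3K4me3 peak closely. The median base-pair Jaccard index was 60.7% for 870 of them, against 23.5% for 303 NP23 peaks of 500 bp or more. The index was taken for each NP23 peak alone, and wide domains are split into several NP23 peaks, which lowers it there. On chromosome 11 from 96132114 to 96184711, for example, 4 NP23 peaks together covered 97.1% of the H3K4me3 peak. Stretches that collect reads in every library would give the close match of short peaks, but short binding sites in short H3K4me3 peaks would as well. A second NP23 or input list was not analysed here.

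H3K27me3 peaks crowded on chromosome 16 of the SCL-LMO1 line (6.05% of its list, 2.97% to 3.79% in the other lines), chromosome 15 of 748T (7.60%, 4.16% to 5.54%) and chromosome 3 of 106A (10.1%, 3.35% to 4.12%). Whether extra chromosome copies crowd them in 106A stays open: the second track over chromosome 3 was 1.27 times the autosomal level and at most 1.01 in the other lines, but chromosomes 5 and 17 of 106A, at 1.15 and 1.14 times, held 4.04% and 2.79% of its peaks, inside the ranges of the other lines. On chromosome 16 of the SCL-LMO1 line, 213 of 295 H3K27me3 peaks lay from 90 to 100 Mb. The same stretch held 94 of 274 in 748T, 88 of 212 in 106A and 237 of 579 in 961C. In the SCL-LMO1 line the second-track ratio there was 2.47, against 0.448 to 0.568 from 0 to 30 Mb and 1.14 over the whole chromosome. From 80 to 90 Mb it was 2.45 as well. That stretch held 6 H3K27me3 peaks, against 3 to 5 in the other lines, whose lists were longer. In the other lines the ratio from 90 to 100 Mb reached at most 1.38, above the bound of 1.2 set for them. The high ratio is thus confined to 1 end of the chromosome in this line, and by that bound the question stays open. In 748T extra copies alone are argued against as enough, because chromosome 14, with as high a second-track ratio as chromosome 15, held 4.13% of the H3K27me3 peaks, inside the 3.82% to 4.30% of the other lines. A difference between the lines in the mark itself was not tested.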

How the results depend on the processing

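Of 136 alternative values for 24 results, 100 kept their direction and their side of the threshold, or for values without a test stayed within the counting interval or 1.5 times the count. The overlap of NP23 with H3K4me3 ran from 36.5% (taller 50% of H3K4me3 peaks) to 99.7% (NP23 peaks of 500 bp or more) and kept its call throughout. Limits on NP23 width, second-track height and H3K4me3 width, and 100 width classes, were chosen after seeing the data. With NP23 peaks of 500 bp or more, overlap with H3K27me3 was 2.96% (permutation p = 0.192). With H3K4me3 peaks of 2 kb or more H3K27me3 met 0.415% of bound peaks (permutation p = 0.727). Among H3K4me3 peaks bound by NP23 peaks of 500 bp or more H3K27me3 kept its excess (3.68% against 0.808%), which rests on 7 peaks. The median width of bound H3K4me3 peaks turned to 3468 bp with the taller 50% of mark peaks and to 4192.5 bp with NP23 peaks of 500 bp or more, both above random placement, since these choices leave out most short peaks. Over H3K4me3 peaks of 2 kb or more, H3K4me3 at bound sites turned to above matched peaks at 91.7% in 748T, 90.9% in 106A and 88.8% in the SCL-LMO1 line, while with NP23 peaks of 500 bp or more it stayed below. H3K27me3 of the other lines at bound sites rests on 1 to 4 peaks and had no call: it turned to above its matched sets with the taller 50% of mark peaks (0.984%, 0.656% and 0.328% in 748T, 106A and the SCL-LMO1 line), the taller 50% of NP23 peaks (0.777%, 0.388%, 0.194%) and NP23 peaks of 500 bp or more (1.58%, 1.05%, 0.526%), and in the SCL-LMO1 line with 100 width classes (0.114%) and broad H3K4me3 peaks (0.415%), and the cause was not tested. The overlap of 106A with 748T was 81.4% for H3K4me3 with lists of equal number and 88.1% with peaks joined within 1 kb, and 6.83% for H3K27me3 with lists of equal number. Leaving out 1 NP23 pre-T line gave 497 to 798 H3K4me3 regions missing in the SCL-LMO1 line, against 352, and 4280 to 4356 H3K27me3 regions private to the SCL-LMO1 line, against 4206. Requiring fewer lines raises such counts by construction. The promoter results by gene list, with promoter windows of 1 and 5 kb or the taller 50% of peaks, were not run for want of gene positions on mm9. No paired analysis was possible because no result comes from a test between groups of samples.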

Other observations

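Tests in this part were chosen after the result was seen, except random placement and lists of equal number for H3K27me3. NP23 peaks of 961C gathered in groups, in part because single domains are split into several peaks. With peaks within 1 kb joined first, 1316 remained of 1629. Grouped within 50 kb, these formed 1159 groups, against 1263 to 1299 with random placement, and 8 groups held 5 or more, where random placement gave 0. Without the joining, 46 groups held 5 or more peaks, so most of those owe their number to peaks less than 1 kb apart. The group with the most NP23-covered bases was on chromosome 11 from 96112201 to 96184458 (59245 bp in 6 peaks). Others were on chromosome 5 from 115712718 to 115799056 (18 peaks), chromosome 17 from 34320627 to 34349443 (14 peaks) and chromosome 4 from 109326090 to 109355620 (14 peaks).

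To the right of the NP23 domain on chromosome 6, H3K4me3 and H3K27me3 peaks overlapped in 961C. The broad H3K4me3 peak, 103 reads tall, ended at 52185551 and the last NP23 peak at 52185869. The first of 8 H3K27me3 peaks (52185579 to 52185835) lay inside that NP23 peak, and the other 7 followed up to 52202229. Of these 7, 5 overlapped low H3K4me3 peaks, of which 961C had 9 between 52187859 and 52199706 with at most 18 reads. In the same stretch H3K4me3 peaks lay at 52186111 to 52186210, 52186515 to 52191544 and 52193482 to 52199793 in 748T, 52188059 to 52190802 in 106A and 52199400 to 52199745 in the SCL-LMO1 line. None of these 3 lines had an H3K27me3 peak between 52140001 and 52200000.

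The share of H3K27me3 peaks found in another line rose with peak width, although most shared peaks of 106A and 748T were short. Of the 459 peaks of 106A that overlapped 748T, 106 were under 200 bp, 223 were 200 to 500 bp and 33 were 1 kb or more. Among 106A peaks, 4% of those under 200 bp and 28.2% of those of 1 kb or more overlapped 748T, where random placement gave 0.139% and 0.681%. For overlap with 961C the shares under 200 bp and at 1 kb or more were 8.87% and 56.4% of 106A, 12.2% and 50.7% of 748T, and 5.76% and 26.1% of SCL-LMO1 peaks, with 0.501% to 0.538% and 1.18% to 1.56% under random placement.

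Few H3K27me3 peaks were shared between lines, and the values argue against positions drawn evenly along each chromosome. The 459 peaks of 106A that overlapped 748T were 40.1 times the mean of random placements, of which the highest gave 24. Placement took no account of where reads can map, so this excess does not by itself show a shared mark. Shortening the lists could not decide on unequal list lengths, since it only removes peaks and could give at most 9.42% (6.83% was found). However, each share was asked of the shorter list, and it ran from 3.02% to 18.2%. The lists of 106A (5600 peaks) and the SCL-LMO1 line (4875 peaks) were close in length. They shared 5.42% of SCL-LMO1 peaks, against 83.3% of 106A peaks for H3K4me3. These values argue against unequal length alone, most directly for that pair. That each list holds a part of the marked stretches of its line is a candidate explanation for 748T and 106A against 961C, where sharing over random placement was higher for peaks of 1 kb or more than for peaks under 200 bp (34.7 against 22.8 times and 36.1 against 17.7 times, intervals apart). For 106A against 748T (41.4 and 28.8 times) and the SCL-LMO1 line against 961C (22.0 and 11.4 times) the intervals overlapped. A difference between lines in where the mark lies was not tested.

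A hypothesis for the widest NP23 domains is that they are homeobox gene clusters. The widest, at 52.6 kb and 29.1 kb, lie on chromosomes 11 and 6, which carry the mouse Hoxb and Hoxa clusters. An mm9 annotation was not used here, so the genes in these domains were not looked up and the hypothesis could not be decided.

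Peaks on Y chromosome sequences were listed in 961C, with 17 for H3K4me3, 14 for NP23 and 5 for H3K27me3, and in no other line. The second track was 0 over 16, 13 and 5 of them. Over X chromosome H3K4me3 peaks its height was 0.846 times the autosomal level in 961C. It was 0.460 times in 748T, 0.658 times in 106A and 0.516 times in the SCL-LMO1 line. Whether 961C carries a Y chromosome was not tested.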
